A study of Halobacterium salinarum NRC-1 with 28 samples.

How the data were processed

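RNA from cultures of Halobacterium salinarum NRC-1, a salt-loving archaeon, was compared with a reference RNA on 2-colour spotted arrays of 70-base oligonucleotides. Per the labels, each sample was taken at a stated time and optical density (OD600) from medium with 20 µg/ml uracil, and the sample and the reference carried Alexa 546 and Alexa 647 or the reverse. The 28 arrays covered 7 times. At each time 2 OD600 values occurred, and each value was shared by 2 arrays with opposite dyes. Arrays with the same time and OD600 were therefore taken as a technical dye flip of RNA from 1 flask, which gave 14 flask samples and 2 flasks per time. The series design text mentions duplicate flasks. It was not stated which samples of different times came from the same flask, so the flask numbers 1 and 2 name samples and were not used as pairs in the main fit. Each number coincides with 1 of the 2 series of array numbers. No culture without uracil was among the samples, so that no effect of uracil could be measured.

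Each array came with the scanner's table of spot and background intensity for both dyes, deposited without normalization. The deposited value table holds the authors' log10 ratios, which per the series design text were made from the raw data with a maximum likelihood method. Set against the scanner values, each column of that table correlated with log10 of Alexa 546 over Alexa 647 at r between 0.927 and 0.998 once spots were ordered row by row across the slide, and at r between -0.01 and 0.12 in the order of the scanner tables. Its ratios thus ran from Alexa 546 to Alexa 647 on every array, with the sign not turned for the dye flip. The medians of its columns lay between -0.0439 and 0.114. How it was centred stayed unknown. Its columns also held exact zeros, up to 3602 of 10752 spots on the array of flask 2 of 2280 min with the culture in Alexa 546. What these zeros stand for stayed unknown. They were kept as log ratios of 0 where the authors' log ratios were used.

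The scan at high sensitivity was used. Median spot intensity was corrected with median local background by normexp with an offset of 50, and log ratios were normalized by loess within each array with limma 3.58.1 in R 4.3.3. Ratios were turned to culture over reference by the dyes in the labels. The 10752 spots formed 2688 probe sets of 4 spots, which were averaged, and the dye-flip arrays of a flask were then averaged to 1 replicate. A limma model with the 7 times as groups was fitted to the 14 flasks, leaving 7 residual degrees of freedom per probe set. A moderated F test covered all differences between times, and moderated two-sided contrasts covered the 6 steps between neighbouring times and the first against the last time. P-values were adjusted by the Benjamini-Hochberg method over all 2688 probe sets within a comparison, and sets with an adjusted p under 0.05 were called. Adjusted p-values given for single genes come from this limma fit. Changes are log2 differences of ratios to the reference, with the standard error (SE) of the fit, and values at a time are means ± SD of 2 flasks. The number of arrays limits the precision: the median SE of a difference between 2 times was 0.12.

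Gene names came from a platform annotation dated to an older release. It gave 1 symbol each to 133 probe sets, none had several, and 2555 sets are unnamed here. Blank and control sets among the unnamed ones were not marked in the sources used here and stayed in the fit. No coordinates were used, because the annotation table at hand is of another strain. Genes were named in the text by a rule: among called, named genes whose flasks did not overlap between the times, the 10 largest rises and 10 largest falls from 540 to 3120 min, the 6 and 6 largest from 1260 to 1860 and from 2280 to 2760 min, and the 3 and 3 largest for every other step. All members of the pyrimidine lists and the 2 to 4 members with the smallest p of each described list were added. The rule, the tests, 28 gene lists and most alternatives were fixed before the data were examined. A gene joined a list by its symbol, since product names were not used here. Of the 28 lists, 12 had no member, 10 had at least 3 and were tested, and 6 were too small to test. Another 7 lists were added once the symbols, but not the values, had been seen. List shifts were tested with limma's camera at its preset correlation of 0.01 for 540 to 3120, 1260 to 1860 and 2280 to 2760 min, adjusted over the 30 tests of the fixed lists and apart from that over the 21 tests of the added lists. The tests were repeated with an estimated correlation, where camera uses the 7 residual degrees of freedom, so a lost call need not come from the correlation.

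A probe set was taken as above background on an array when the culture's spot median was at least 1.5 times the local background in 2 or more of its 4 spots. Where a named gene was above background on no array of a time, its change is given as a bound: channel values after loess and Aquantile normalization were averaged per flask, and the dim time was set at the lowest signal among sets above background on each array, or at the gene's own signal if that was higher. Such bounds compare single channels between arrays, without the reference, and can exceed the fold from the ratios. Where they do, the log2 difference of ratios is given beside the single-channel bound, and the adjusted p belongs to that difference. No fold is given where both times were dim. The gene csg was saturated, at 65535, on every array and has no fold.

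The fit was tested on simulated data, with 200 of 2688 sets changed. Noise was drawn independently per set and flask with variances from the fitted limma prior, and the same model was refitted. The false share was thus largely set by the adjustment, and errors of scaling or of a single flask were not covered. For 2280 to 2760 min, 59.8% of changes of 0.5 on the log2 scale and 94.8% of changes of 1 were recovered, and 4.8% of the calls were false. For 2760 to 3120 min the recovered shares were 60.6% and 94.9%, and 5.21% of the calls were false. The chain from intensity to contrast was tested by doubling the culture's signal over local background at 3120 min in 40 sets of each of 5 ranges of signal. Against a log2 change of 1, the median recovered from 2760 to 3120 min was 0.80 above 3000 units, 0.83 from 1000 to 3000, 0.59 from 300 to 1000 and 0.30 from 100 to 300. Below 100 units it was -0.36, where doubling a signal under the local background lowers it. Of the doubled sets, 95% were called higher above 3000 units, 100% from 1000 to 3000 and 80% from 300 to 1000. The share was 22.5% from 100 to 300 units and 0% below 100, so the shares of the simulated data do not hold for dim sets. With all 200 sets doubled, the median of the other sets moved by -0.15 above 3000 units and by -0.07 from 1000 to 3000, so that part of the shortfall of bright sets came from the check itself. In a check added after these values were seen, 20 sets of each range were doubled and 20 halved. The medians recovered were 0.95 and -0.95 above 3000 units, 0.93 and -0.77 from 1000 to 3000, 0.65 and -0.49 from 300 to 1000, and 0.34 and -0.24 from 100 to 300. Up to 100 units, a range of 1109 sets, they were -0.19 and 0.30, so that the median direction was reversed there. Fold changes of sets from 100 to 1000 units were thus understated in both checks, and those of sets above 3000 units little in the balanced one. The direction of a change up to 100 units was not recovered in either check. The expectation first set for this check, a median above 0.8 over sets brighter than 500 units in Alexa 546, was not met. A later one, that recovery would rise with every range of signal, was not met either, and both were replaced by the values per range.

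The alternatives were no background subtraction, an offset of 0, median centring, scaling between arrays, the authors' log ratios, leaving out the dimmest 20% of sets, all 28 arrays with a dye term and the flask as a random block, arrays of either dye alone, the 2 series of array numbers as a block, only the flasks of the 2 times compared, trend and robust empirical Bayes, the median of spots, and leaving out each flask in turn. Mean in place of median pixel intensity, the named genes alone as background of the list test, and the list of proteasome and chaperones without panB, were added after seeing the data. Figures were drawn with matplotlib 3.10.9.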

Results

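Transcript levels of Halobacterium salinarum NRC-1 were followed on 28 arrays at 7 times of growth in medium with uracil, with 2 flasks per time and 2 dye-flip arrays per flask. The mean OD600 rose from 0.203 at 540 min to 0.430 at 890 min and 0.799 at 1260 min. It was 0.897 at 1860 min and 0.879 at 2280 min, and then reached 1.09 at 2760 min and 1.32 at 3120 min. Flasks of the same time correlated across probe sets at r between 0.825 and 0.937, and the dye-flip arrays of a flask at r between 0.514 and 0.892. Of 2688 probe sets, 1551 (57.7%) changed over the 7 times by the moderated F test of limma, and these included 102 of the 133 named genes.

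**Figure D1:**
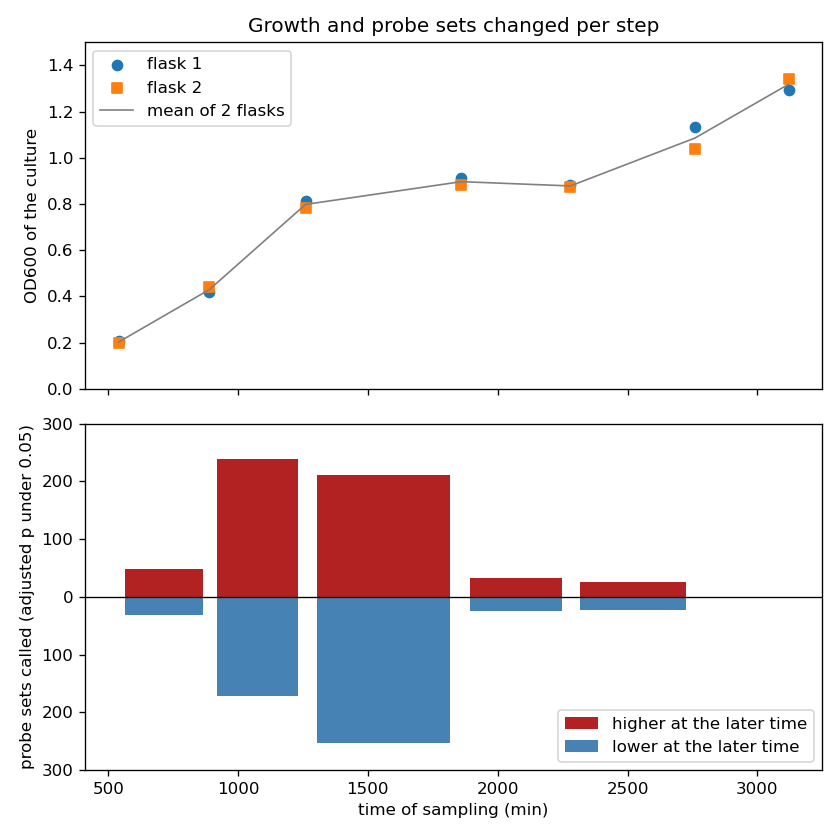
The upper panel plots OD600 against the time of sampling in minutes for each flask, with a line through the means of 2 flasks. The lower panel plots the number of probe sets called higher (upward) or lower (downward) at the later time of each step, with 410 sets from 890 to 1260 min, 464 from 1260 to 1860 min and 0 from 2760 to 3120 min.

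The first and the last sample were compared to ask how the dense culture differed from the sparse one. The ribosomal protein gene rpl12p fell by 1.86 on the log2 scale (SE 0.10), from -0.25 ± 0.01 to -2.11 ± 0.07 (SD, n = 2), and rpmC, whose symbol is that of another ribosomal protein, fell by 1.64 (SE 0.11). Of 12 aminoacyl-tRNA synthetase genes, which charge tRNAs with amino acids, 8 fell and 0 rose, with lysS at -0.90, serS at -0.84, thrS at -0.62 and pheS, above background on 1 of 4 arrays at 3120 min, at -0.42. Of 6 citric acid cycle genes 5 fell and 0 rose. The succinate-CoA ligase genes sucC and sucD fell by 1.41 (SE 0.08) and 1.32 (SE 0.08), and the malate dehydrogenase gene mdh fell by 1.30 (SE 0.10). The glycolytic enolase gene eno fell by 1.01, the glutamine synthetase gene glnA fell by 1.06 and cobN, of cobalamin synthesis, fell by 1.32.

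The largest rise from 540 to 3120 min among the named genes was that of argH, the gene of argininosuccinate lyase, the last enzyme of arginine synthesis. Its log2 ratio went from -0.37 ± 0.21 to 2.15 ± 0.04 (SD, n = 2), a difference of 2.52 (SE 0.12) or 5.74-fold, with 1 of 4 arrays above background at 540 min. The glutamate dehydrogenase genes went apart: gdhB rose by 1.21 (SE 0.10), whereas gdhA1 fell by 1.44 (SE 0.08) and gdhA2 fell by 0.44 (SE 0.11). The serine synthesis gene serB rose by 1.10 (SE 0.14) and dpsA, of a ferritin-like DNA-binding protein, by 0.75 (SE 0.10). The ratio of the purine synthesis gene purF rose by 0.71 (SE 0.17). However, purF was above background on every array at 540 min and on only 2 of 4 at 3120 min. Of the purine genes next in p, purE and purD differed by 0.37 and 0.42, but purL by -0.52. Like purF, purD was above background on fewer arrays late, on 2 of 4 at 540 min and 1 of 4 at 3120 min. The gene bat, an activator of bacteriorhodopsin genes, was not well above background at 540 min. Its ratio rose by 1.38 (adjusted p = 6.27e-05 in limma), with a single-channel bound of 4.15-fold. Of 11 chemotaxis genes 8 rose and 1 fell. The transducer genes htr8, htr7 and htr1 rose by 0.91, 0.72 and 0.63. The ratio of htr18 rose by 1.35 (single-channel bound 4.01-fold) from a level not well above background. The ratio of the transducer gene htr4 fell by 1.04 (single-channel bound 2.56-fold), to a level not well above background. Of 5 genes of other rhodopsins and their transducers 3 rose, namely sop1 by 0.65, htr1 by 0.63 and hop by 0.51. The histidine breakdown gene hutG also passed the test, but it was not well above background at either time and has no fold.

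In all, 1362 probe sets were called from 540 to 3120 min, with 658 higher and 704 lower at 3120 min, and 28 of the named genes were higher and 54 lower. With the dimmest sets left out, the 1246 calls were 546 higher and 700 lower, and the median of the remaining sets was -0.07. The number of higher calls thus depended more on dim sets than that of lower calls. In the checks of the chain from intensity to contrast, the direction of changes in the dimmest range was not recovered. Directions of the dimmest sets are therefore not settled. The camera test called the aminoacyl-tRNA synthetases (adjusted p = 0.0084) and the citric acid cycle (adjusted p = 0.0084) as lower and the chemotaxis genes as higher (adjusted p = 0.0084). With an estimated correlation none of these held (adjusted p = 0.156, 0.156 and 0.189). For the aminoacyl-tRNA synthetases that correlation was 0.0052, below the preset 0.01, so their loss did not come from a higher correlation. In the authors' log ratios the median of all sets was shifted by 0.21 between these times, and the 1608 sets called there were 1103 higher and 505 lower, so that directions hold relative to the bulk of the probe sets.

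**Figure D2:**
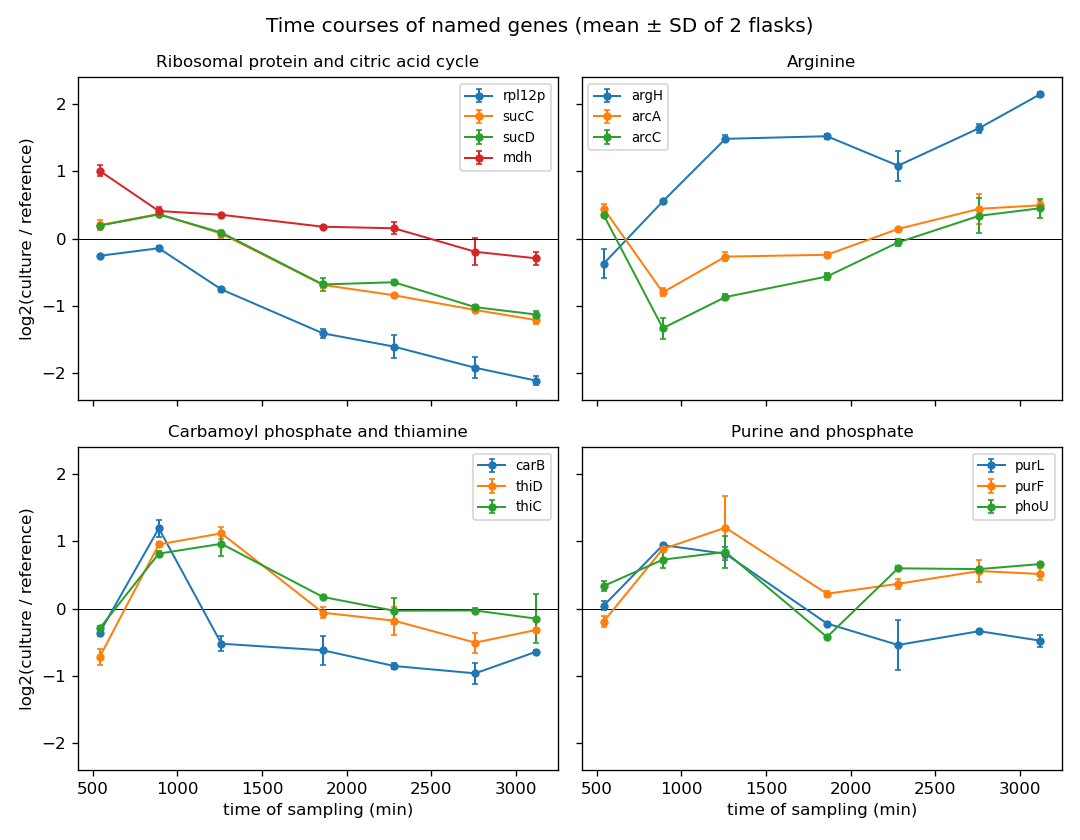
Each panel plots log2 of culture over reference against the time of sampling in minutes for named genes, with points and bars for the mean ± SD of 2 flasks. The gene rpl12p went from -0.25 at 540 min to -2.11 at 3120 min, argH from -0.37 to 2.15, and carB was at 1.19 at 890 min and not well above background from 1260 min on.

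From 1260 to 1860 min the mean OD600 rose from 0.799 to 0.897. Of 7 purine synthesis genes 4 fell and 0 rose, after a rise of the same 4 from 540 to 890 min. The largest falls were in purL by 1.04 (SE 0.14) and purF by 0.98 (SE 0.17), followed by purM by 0.75 (SE 0.12) and purD by 0.51 (SE 0.13), which were above background on 1 and 2 of 4 arrays at 1860 min. All 3 thiamine synthesis genes fell, thiD by 1.18 (SE 0.11), thiC by 0.79 (SE 0.15) and thiL by 0.40 (SE 0.08). The gene phoU, of phosphate regulation, went from 0.84 ± 0.24 to -0.42 ± 0.02 (SD, n = 2) and fell by 1.27 (SE 0.11). It rose again by 1.02 (SE 0.11) by 2280 min. The genes glnA, sucD and sucC fell by 0.85, 0.77 and 0.76, rpl12p fell by 0.65 and cobN fell by 0.53. Among 5 genes of the list of proteasome and chaperones, dnaK and psmB fell by 0.43 and 0.38. The list holds panB by its symbol, which can also mean an enzyme of another pathway. Fewer named genes rose, 8 against 29 that fell. The chemotaxis kinase gene cheA rose by 0.61 (SE 0.11), cheB by 0.40 (SE 0.07) and cheR by 0.32 (SE 0.09). The halorhodopsin gene hop rose by 0.48 (SE 0.10), the sensory rhodopsin gene sop1 by 0.33 (SE 0.09), gdhB by 0.39 (SE 0.10) and bat, above background on 2 of 4 arrays at 1260 min, by 0.73 (SE 0.17).

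Of the 464 probe sets called in this step 211 were higher and 253 lower at 1860 min. With median centring the 516 calls were 177 higher and 339 lower. The count was 246 without flask 1 of 1260 min, 284 without flask 2 of 1260 min, 261 without flask 1 of 1860 min and 302 without flask 2 of 1860 min. Camera called purine synthesis (adjusted p = 0.0084), the citric acid cycle (adjusted p = 0.0146) and the proteasome and chaperones (adjusted p = 0.0195) as lower, and chemotaxis genes (adjusted p = 0.0084) and the other rhodopsins (adjusted p = 0.049) as higher. With an estimated correlation none held (adjusted p from 0.156 to 0.189). Thiamine synthesis, a list added later, was called lower at adjusted p = 0.0062, with adjusted p = 0.453 at an estimated correlation. Without panB, a choice made after seeing the data, the proteasome and chaperones had adjusted p = 0.0419, and adjusted p = 0.189 at an estimated correlation.

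From 2280 to 2760 min OD600 rose again, and 48 probe sets were called, with 26 higher and 22 lower. This split turned to 59 higher and 82 lower with the flask as a random block, and to 41 and 57 with mean pixel intensity. In the authors' log ratios it was 20 higher and 11 lower. The named genes that rose were serB by 0.83 (SE 0.14), argH by 0.56 (SE 0.12), htr8 by 0.53 (SE 0.10), the methionine sulfoxide reductase gene msrA, above background on 2 of 4 arrays at 2280 min, by 0.50 (SE 0.08) and the proteasome gene psmA by 0.40 (SE 0.08). Those that fell were the cysteinyl-tRNA synthetase gene cysS by 0.59 (SE 0.12), sucD by 0.37 (SE 0.08) and cbiG, of cobalamin synthesis, by 0.37 (SE 0.08). Camera called the citric acid cycle (adjusted p = 0.0084) and the cobalamin genes (adjusted p = 0.0084) as lower and the proteasome and chaperones as higher (adjusted p = 0.0426), and with an estimated correlation none held (adjusted p = 0.156, 0.189 and 0.189). Without panB the last had adjusted p = 0.00982, and adjusted p = 0.138 at an estimated correlation. These calls rested on few flasks and on the scaling. In the fit with all 28 arrays the correlation between arrays of a flask was estimated at 0.085, so dye-flip arrays counted almost as separate replicates. The count was 0 without flask 1 of 2760 min, 3 without flask 1 of 2280 min, 7 with median centring, 3 with scaling between arrays, and 141 with all 28 arrays and the flask as a random block.

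The steps from 1260 to 1860 min and from 2280 to 2760 min, which share no array, were compared to ask whether genes went back. The mean OD600 rose in both, and the step between them, in which it went from 0.897 to 0.879, was not part of this comparison. Of the sets called in both steps 7 went in opposite directions, against 4.17 expected from independent lists, and 5 in the same direction, against 4.11. The count of 7 was 0 to 6 with a flask left out, 0 with median centring and 29 with the flask as a random block. The changes of the steps correlated across probe sets at r = -0.05 (Spearman rho -0.05), where probe sets are not independent replicates. The gene serB was among the 7, with a fall by 0.73 and then a rise by 0.83, and sucD fell in both steps.

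In the other steps a few named genes made large moves. From 540 to 890 min, 81 probe sets were called, with 49 higher and 32 lower. The gene thiD rose by 1.68 (SE 0.11), thiC by 1.11 (SE 0.15) and carB, of the large subunit of carbamoyl phosphate synthetase, by 1.55 (SE 0.12), from a time at which it was above background on 1 of 4 arrays. Of 7 purine synthesis genes 4 rose and 0 fell (median of the list 0.85): purF by 1.08 (SE 0.17), purD by 0.94 (SE 0.13), purL by 0.90 (SE 0.14) and purM by 0.85 (SE 0.12). At 540 min purD was above background on 2 and purM on 3 of 4 arrays. Without flask 1 of 890 min the adjusted p was 0.0605 for purF and 0.0596 for purL, without flask 1 of 540 min it was 0.0570 for purF and without flask 2 of 540 min 0.0559 for purL. The purine genes of this step, and arcA and arcC in the next, were named after their values were seen. The arginine fermentation genes arcC and arcA, of carbamate kinase and arginine deiminase, fell by 1.68 (SE 0.12) and 1.25 (SE 0.10), and mdh fell by 0.60 (SE 0.10). From 890 to 1260 min, 410 sets were called, with 238 higher and 172 lower, and with median centring 218 were higher and 266 lower. In that step arcA and arcC rose by 0.53 (SE 0.10) and 0.46 (SE 0.12), of which arcA missed the threshold without flask 1 of 890 min (adjusted p = 0.0669) and arcC without any 1 of the flasks of 890 and 1260 min (adjusted p up to 0.195). The call of arcC was also lost with median centring and with either dye alone. The gene argH rose by 0.93 (SE 0.12), pan1 by 0.80 (SE 0.14) and dpsA by 0.67 (SE 0.10). The genes rpl12p and lysS fell by 0.61 and 0.57. The ratio of carB fell by 1.72 (single-channel bound 5.15-fold), to a level not well above background. From 1860 to 2280 min 57 sets were called, with 33 higher and 24 lower, and the named ones were phoU, pan1 and mch. The ratio of pan1 fell by 0.99 (single-channel bound 2.46-fold), to a level not well above background. The gene mch fell by 0.45 (SE 0.10) and was above background on 1 of 4 arrays at either time. From 2760 to 3120 min limma called 0 sets, with 258 at an unadjusted p under 0.05 and a smallest adjusted p of 0.172. Changes of dim sets can be missed in this step. When the culture's signal was doubled at 3120 min, 22.5% of sets from 100 to 300 units and 0% of those below 100 were called higher. Leaving out 1 flask gave as few as 26 sets from 540 to 890 min and 127 from 890 to 1260 min, both without flask 1 of 890 min, and 20 from 1860 to 2280 min without flask 2 of 1860 min.

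Pyrimidine genes were read throughout because the medium held uracil. Of 5 pyrimidine synthesis genes, pyrF, of orotidine phosphate decarboxylase, fell by 0.68 (SE 0.12) from 540 to 3120 min, where 2 of 4 arrays were above background, and 0 rose. The differences were 0.31 (SE 0.13) for carA, -0.13 (SE 0.08) for pyrI and 0.00 (SE 0.09) for pyrB, and none of these 3 passed the test. The gene carB, above background on 1 of 4 arrays at 540 min and not well above it at 3120 min, has no fold and did not pass the test either (adjusted p = 0.0684). From 890 to 1260 min 3 of the 5 fell and 0 rose (median of the list -0.44), namely carB, pyrF by 0.49 (SE 0.12, adjusted p = 0.019) and carA by 0.44 (SE 0.13, adjusted p = 0.0366). At 1260 min pyrF and carA were above background on 3 of 4 arrays. Both calls were lost with an offset of 0 and with either dye alone, and that of carA with median centring too. Without any 1 of the flasks of 890 and 1260 min pyrF missed the threshold (adjusted p up to 0.114), and so did carA (adjusted p up to 0.19), which also missed it without either flask of 540 min (adjusted p = 0.0501), whereas carB kept its call with each flask left out. Of the other steps, carB rose from 540 to 890 min and no other gene of the list was called. The list of pyrimidine uptake, salvage and breakdown, called the salvage list here, held only dcd, tmk and deoC. Of these 3 genes, dcd, of dCTP deaminase, was at least 1.53-fold lower at 3120 min, to a level not well above background. Of the single steps, the salvage list had a call only from 1260 to 1860 min, where dcd fell by 0.47 (SE 0.14, adjusted p = 0.0465) and was above background on 2 of 4 arrays at 1860 min. It missed the threshold without any 1 of the flasks of 540, 1260, 1860 and 3120 min (adjusted p up to 0.214). The gene tmk, above background on 1 of 4 arrays at 540 min and not well above it at 3120 min, has no fold and did not pass the test (adjusted p = 0.0545), and deoC was not well above background at either time. Camera did not call the pyrimidine synthesis list (adjusted p = 0.66) or the salvage list (adjusted p = 0.271) from 540 to 3120 min.

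The spread of ratios to the reference was compared between times because the labels and the series design text describe the reference RNA differently. Per the labels it was a mid-log culture at OD600 of 0.5 to 0.6 in standard medium, and per the design text it came from the last sampling of a repeat culture. The SD of log2 ratios across probe sets was lowest at 890 min, with 0.293 and 0.279 in the flasks. It was 0.358 and 0.350 at 540 min, 0.457 and 0.400 at 1260 min, and 0.679 and 0.615 at 3120 min. The SD at 3120 min thus exceeded that at 890 min in both flasks by more than the 0.0644 between the flasks of 3120 min.

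**Figure D3:**
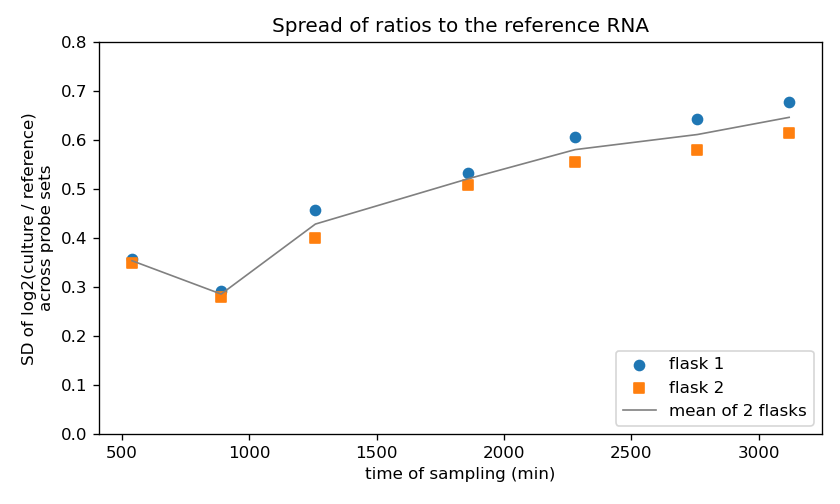
The plot shows the SD across probe sets of log2 of culture over reference against the time of sampling in minutes, with a point per flask and a line through the means of 2 flasks. The mean was 0.286 at 890 min and 0.647 at 3120 min.

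In other lists from 540 to 3120 min, the gyrase genes gyrA and gyrB fell by 0.80 (SE 0.09) and 0.54 (SE 0.13), and orc7, of a replication origin protein, rose by 0.26 (SE 0.08). The histidine synthesis gene hisF fell by 0.76 (SE 0.15) and 3 of 6 genes of that list fell, of which hisB and hisD were not well above background at 3120 min. The genes dnaK and psmA differed by -0.62 (SE 0.08) and 0.40 (SE 0.08), and psmA turned to -0.0737 with median centring. The oxidative stress gene msrA rose by 0.69 (SE 0.08), phoU rose by 0.33 (SE 0.11), secY of protein export fell by 0.75 (SE 0.12), and the repair gene uvrB rose by 0.41 (SE 0.11). The list tests of DNA replication, histidine synthesis, histidine breakdown, aromatic amino acid synthesis, glutamate dehydrogenases, DNA repair and protein export passed in none of the 3 comparisons. Adjusted over the list alone, the citric acid cycle had 5 members called from 540 to 3120 min against 5 over all sets, the chemotaxis genes 9 against 9, the aminoacyl-tRNA synthetases 8 against 8, and the pyrimidine salvage list 2 against 1. From 1260 to 1860 min purine synthesis had 4 against 4 and the proteasome and chaperones, panB included, 4 against 2. Of the 51 list tests, the median or mean of the members went against the test's direction in 12, of which 0 were called.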

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

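Mean pixel intensity, the named genes as background and a list without panB were alternatives chosen after seeing the data; the others were planned. The count over all 7 times (1551) ranged from 1183 to 1742 and that from 540 to 3120 min (1362) from 989 to 1608 over the alternatives, and from 1338 to 1595 and from 1011 to 1388 with a flask left out, all within 1.5 times. A time left with 1 flask is assumed to vary like the others. The time of the lowest spread to the reference was 890 min under all 5 alternatives run for it. Of these, scaling between arrays evens out the spread itself (0.414 at 890 min, 0.494 at 3120 min) and so says little about it. Not all calls of named genes were followed, but only 115 of genes chosen by the naming rule or named after their values were seen. Of these, 81 (Alexa 647 alone) to 114 (random block) held in the other alternatives. They were chosen for large changes or small p in the same data, so the share need not hold for other calls.

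For 540 to 890 min (81 sets) scaling between arrays gave 194, the random block 150, Alexa 546 alone 46, Alexa 647 alone 31 and only the flasks compared 30, with 26 to 91 when a flask was left out. For 890 to 1260 min (410) Alexa 546 alone gave 168 and Alexa 647 alone 158, with 127 to 446 for flasks left out. For 1260 to 1860 min (464) they gave 246 and 278, with 246 to 485. Median centring moved the split of 890 to 1260 min from 238 higher and 172 lower to 218 and 266. For 1860 to 2280 min (57) the random block gave 92, Alexa 546 alone 34 and only the flasks compared 34, with 20 to 61. For 2280 to 2760 min (48) an offset of 0 gave 25, median centring 7, scaling 3, the authors' log ratios 31, the random block 141, Alexa 546 alone 1, Alexa 647 alone 1, only the flasks compared 0 and mean pixel intensity 98, with 0 to 42. For 2760 to 3120 min (0) the random block gave 3 and mean pixel intensity 2, with 0 for every flask left out. Opposite changes (7) were 4 with an offset of 0, 0 with median centring, 2 with scaling, 3 in the authors' log ratios, 29 with the random block, 0 with Alexa 546 alone, 0 with Alexa 647 alone and 0 with only the flasks compared, with 0 to 6. Fewer arrays or flasks entered the fits by dye and by flask, and the random block counted dye-flip arrays almost as separate replicates. Otherwise the cause was not tested. List shifts (11) were 0 with an estimated correlation, where camera uses the 7 residual degrees of freedom, 5 against the named genes alone and 11 without panB; with a flask left out they were 9 to 11.

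The directions that turned were those of changes from 540 to 3120 min. Median centring gave -0.39 for arcC, -0.37 for arcA and -0.0737 for psmA, and the authors' log ratios gave -0.35, -0.37 and -0.0588 for them and 0.22 for carB, 0.33 for hisD, 0.20 for trpB and 0.52 for mutL. Of these, carB, hisD and mutL were not well above background at 3120 min and trpB at neither time, so that their directions are not settled by either setting. The cause was not tested. The replicate block by array number series called 1652 sets over all times and 101, 509, 563, 68, 58, 0 and 1430 in the comparisons, 9 opposite changes and 10 list shifts, each within 1.5 times. Deviations of flasks in a series correlated between times at 0.0519 to 0.302 (21 pairs, median 0.124). All were positive, so flasks of a series shared part of their deviation. A shared culture and a shared run of arrays cannot be told apart here, and the main fit took the flasks as independent. Signal over background limits the late times, where 1119 sets at 3120 min were above background on no array against 700 at 540 min.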

Other observations

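The tests on probe sets above background and on the purine and thiamine lists were chosen after the result was seen.

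The arginine genes followed different courses. The fermentation genes arcA and arcC were at their lowest mean at 890 min, -0.80 ± 0.06 and -1.33 ± 0.16 (SD, n = 2), and stood at 0.50 ± 0.06 and 0.45 ± 0.14 at 3120 min, where they differed from 540 min by 0.05 (SE 0.10) and 0.10 (SE 0.12), which did not pass the test. With median centring these differences were -0.37 and -0.39 and passed it. The synthesis gene argH was at 1.49 ± 0.05 by 1260 min and 1.09 ± 0.22 at 2280 min.

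The descriptions of the reference RNA disagreed, and the spread of ratios was used to weigh them. A reference from the final time point would give the lowest spread at 3120 min, but it was lowest at 890 min and higher at 3120 min in both flasks, which argues against that origin. A mid-log reference predicts a lowest spread at 890 or 1260 min, and the mean SD of 0.286 at 890 min is consistent with it. The cultures held uracil and, per the labels, the reference did not carry that note, so an effect of uracil on the spread stays open.

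Fewer probe sets stood above background in the culture's channel at later times. The number on no array rose from 700 at 540 min to 1119 at 3120 min. Fainter arrays as a whole are argued against, since the number in the reference's channel went from 555 to 596, 0.0979 of the rise in the culture's. A failure of 1 dye is argued against too, since the percentage of sets above background fell by 14.5 percentage points with the culture in Alexa 546 and by 18.0 with it in Alexa 647. Weaker labelling of late culture RNA and fewer abundant transcripts in late cultures may each account for it and stay open, and neither was tested. The count is relative to local background, which changed too. From 540 to 3120 min its median in the culture's channel went from 320 to 557 (Alexa 546) and from 573 to 861 (Alexa 647) in flask 1. In flask 2 it went from 349.5 to 351 and from 336 to 462. Spot medians went from 684.5 to 737 and from 1307.5 to 1165 in flask 1. In flask 2 they went from 807 to 568 and from 932.5 to 715. The share of the background in the count was not tested.

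Of the thiamine synthesis genes, thiC and thiD, and of the purine synthesis genes, purD, purF, purL and purM, had their highest mean at 890 or 1260 min, whereas thiL was highest at 540 min and purE at 2280 min. The mean correlation over 14 flasks between 7 purine and 3 thiamine genes was 0.35, above 99.2% of 10000 random pairs of lists matched in size and brightness. This decides nothing, because the pair was picked after its profiles were seen and 38 of 136 pairs of gene lists lie above the 95th percentile of the random pairs (0.202). Nearness on the slide is argued against, since neighbouring probe sets gave 0.0404 of that correlation. The pair ranked 16 of 136 pairs of lists, and its sides differed. Thiamine synthesis correlated more with the citric acid cycle (0.495), histidine synthesis (0.441), cobalamin genes (0.42) and pyrimidine synthesis (0.395). Purine synthesis had thiamine synthesis as its closest list, followed by cobalamin genes (0.189), and it correlated little with the citric acid cycle (0.0669) or the aminoacyl-tRNA synthetases (-0.0369). A broad course common to these lists is thus not shown for purine synthesis, and neither is a link between purine and thiamine synthesis. No biological explanation was tested.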
